A study of Mus musculus with 2 samples.

How the data were processed

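PolyA RNA-seq was measured in whole forebrain of mice of strain B6NCrl on the day of birth (P0, age 0 days). Per the labels, the 2 libraries came from separate pups, pup 1 (replicate 1) and pup 3 (replicate 2), each from a single forebrain and from 10 ng of RNA. RNA was extracted with the mirVana kit, complementary DNA was primed with oligo-dT, and the libraries were made by tagmentation (Nextera) with ERCC spike-in RNAs added. Whether the libraries keep the strand is not stated in the sources used here. Sex was not collected, and the labels give both pups the same donor identifier.

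The authors deposited 2 gene tables and 2 transcript tables per library, for the mouse genome mm10 with annotation releases M21 and M4. Alignments and signal tracks were not used here. The tables hold estimated counts, which the authors deposited in the form of expected counts per gene or transcript, in which reads that map to several places are split. They also hold deposited TPM, scaled by the authors to a fixed total over all listed features with spike-ins and short RNAs included, as point estimates and as posterior means. Values in deposited FPKM, per kilobase of effective length and read depth, stand beside them. The transcript tables hold each transcript's percent of its gene's TPM, as deposited by the authors. The aligner, the quantifier and their versions are not given in the sources used here. The column names are those of RSEM.

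The M21 gene table was used throughout and M4 as an alternative. M21 lists 81881 features, of which 55536 are genes, 97 are spike-in sequences and 26248 carry identifiers made of a number alone. All 55536 gene identifiers had a match in the reference annotation, from which symbols, biotypes and coordinates were taken. Of the 43346 gene identifiers in M4, 42462 had a match once version suffixes were removed. The deposited length exceeded the effective length by 99 bases in 99.99% of the features, so a feature of about that length has a very small effective length and reaches a high TPM on 1 or 2 reads.

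The 2 libraries make 1 group, so no comparison between groups and no p-value was possible. A two-sided exact sign-flip test over 2 pups cannot go below p = 0.5. Differences between the pups are therefore given by size alone. They are coded as log2 of TPM + 1 in pup 3 over TPM + 1 in pup 1, so positive values are higher in pup 3. Errors are SDs over the 2 pups unless stated. A gene was called detected at a TPM of 1 or more. Agreement was described with Pearson r and Spearman rho of log2(TPM + 1) across genes with a mean TPM of 1 or more, and genes are not independent replicates. The biological coefficient of variation (BCV) was fitted in edgeR with an intercept alone, on expected counts rounded to whole numbers, with filterByExpr and TMM scaling. Genes over 2-fold apart were counted among genes with a TPM of 5 or more in at least 1 pup.

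Before the data were examined, 43 gene lists were fixed for cell types, regions, signalling, stress and neighbouring tissues, together with gene pairs, of which 6 are reported here, and 16 genes for isoforms. A list's level is the median of its members' mean TPM, given with the SD of the list's medians in the 2 pups and with its percentile among 10000 random lists of equal size drawn from genes of the members' biotypes. A list's difference is the median log2 ratio of members with a mean TPM of 1 or more, with its percentile among 10000 random lists matched on expression in 20 bins. Lists with under 3 such members were not compared between pups. Log2 ratios of gene pairs were taken within each library with a pseudocount of 0.1. The leading isoform was the transcript with the highest TPM in genes with a TPM of 5 or more in both pups and more than 1 transcript listed. The named genes were fixed by rule: the 20 with the highest mean TPM outside spike-ins and mitochondrially encoded genes, the 4 highest members of each list and any member needed to state a level under TPM 1, the 12 genes with the largest difference in each direction, and all pair, isoform and sex-linked genes. Other genes named are said to have been chosen after their values were seen.

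The libraries held 40964891 (pup 1) and 41230878 (pup 3) expected counts. A read on a transcript of 1000 bases effective length equals 0.0383 TPM in pup 1 and 0.0340 TPM in pup 3. Shares of counts carry 95% Wilson intervals, and a count of 0 was set to a floor of 3 counts per library for ratios. Reads carry no molecular identifiers in these tables, so intervals and floors cover counting error alone.

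Alternatives fixed in advance changed the TPM minimum, the pseudocount, the unit (FPKM, CPM, posterior mean TPM), the scaling between libraries (TMM, and DESeq2 size factors), the low-count filter, the annotation release, and the replicate left out. Alternatives chosen after seeing the data were a minimum of 50 counts, protein-coding genes alone, CPM without scaling, removal of the all-gene median, and log2 ratios with a trend on length and GC content removed. That trend was an additive natural-spline fit with 4 degrees of freedom per term on log length and GC content of each gene's leading transcript of at least 200 bases. It was repeated with the deposited gene-level length. In both fits the median log2 ratio of the fitted genes was kept. Added lists, also written after the data were seen but before their own members' values were looked at, were a second diencephalic list and 4 X-linked genes that escape inactivation.

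The procedure was tested on simulated data. A simulated BCV of 0.05 with no changed genes was fitted as 0.0498, and one of 0.2 with 200 changed genes as 0.210; 200 changed genes raised a BCV of 0.05 to 0.0950. At 200 or more counts and a BCV of 0.2, 49 of 50 genes raised 4-fold and 42 of 42 lowered 4-fold passed 2-fold, as did 150 of 12133 unchanged genes. Of 100 unchanged lists, 5 lay outside the central 95% of matched lists. Genes were simulated independently of each other and without a length trend. That share therefore does not carry over to real lists, whose genes can vary together. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, patsy 1.0.2 and matplotlib 3.10.9.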

Results

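The libraries measured polyadenylated RNA in the forebrain of newborn mice, the part of the brain that holds the cerebral cortex, striatum, thalamus and hypothalamus. The 2 libraries formed 1 group, pup 1 and pup 3, with no treatment and no second group in the labels. The comparisons therefore asked which genes and cell types the newborn forebrain expressed, at which levels, and by how much the 2 pups differed. The total was 40964891 expected counts in pup 1 and 41230878 in pup 3. In pup 1, 15864 genes reached a TPM of 1, and in pup 3 15010 genes did. Both pups shared 14753 of the 55536 listed genes, of which 13113 were protein coding, 299 lincRNA genes, 294 antisense genes and 456 processed pseudogenes. A further 1111 genes reached a TPM of 1 in pup 1 alone and 257 in pup 3 alone.

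Protein-coding genes took 95.1% ± 0.545 of the counts (SD, n = 2 pups) and lincRNA genes 0.648% ± 0.0951. The mitochondrial chromosome took 2.47% of the counts in pup 1 (95% Wilson interval 2.47 to 2.48) and 3.56% in pup 3 (3.55 to 3.57). That share leaves out reads assigned to nuclear pseudogenes that resemble mitochondrial DNA, such as Gm28437 with 222250 counts in pup 1 and 308303 in pup 3. Genes for cytosolic ribosomal proteins took 1.51% in pup 1 (1.5 to 1.51) and 2.06% in pup 3 (2.06 to 2.07). Spike-in RNAs held 334 counts over 21 of the 97 sequences in pup 1 and 278 counts over 17 in pup 3. Their share was 0.000815% in pup 1 (0.000732 to 0.000908) and 0.000674% in pup 3 (0.000600 to 0.000758), too few counts to scale the libraries by.

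Genes of the cytoskeleton were among the most abundant protein-coding genes. Tuba1a (ENSMUSG00000072235, chromosome 15, 98949837 to 98953703), the alpha tubulin of newborn neurons, stood at 16797 ± 2421 TPM (SD, n = 2 pups here and for every value given with ± in TPM; for a gene list, the SD of the list's median in each pup). Actb (chromosome 5, 142903115 to 142906754) followed at 16483 ± 701 TPM, but its leading transcript was 241 bases long, so part of its TPM rests on a short entry. Actg1, with a leading transcript of 1952 bases, stood at 3438 ± 257 TPM. Stmn1, a regulator of microtubule assembly, reached 6363 ± 499 TPM, and the actin-binding thymosins Tmsb4x and Tmsb10 reached 5304 ± 811 TPM and 5088 ± 453 TPM. Cfl1, which severs actin filaments, stood at 3639 ± 217 TPM. Nnat, an imprinted gene of the developing brain, reached 5438 ± 547 TPM. Ppia, Ftl1 and Ubb, genes of protein folding, iron storage and ubiquitin, stood at 5026 ± 770 TPM, 4758 ± 253 TPM and 3959 ± 149 TPM.

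Other entries among the 20 highest were copies or overlaps that short reads cannot place with certainty. Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle, carried identical values of 11940 ± 4367 TPM. Gm28437, Gm29216 and Gm28661 are neighbouring pseudogenes on chromosome 1 that resemble mitochondrial DNA, at 13883 ± 2032 TPM, 5448 ± 753 TPM and 3613 ± 306 TPM. CT010467.1, annotated as ribosomal RNA, stood at 6501 ± 276 TPM, the processed pseudogene Gm10123 at 4390 ± 535 TPM, and Gm22133, a microRNA entry within Ftl1, at 3822 ± 189 TPM. Of the genes encoded in mitochondria, mt-Atp6 reached 14252 ± 3449 TPM and mt-Nd1 5297 ± 720 TPM, mt-Cytb 4573 ± 897 TPM, and mt-Atp8, which overlaps mt-Atp6, 11001 ± 2169 TPM. The list of 13 such genes had a median of 2017 ± 627 TPM. The 83 genes for cytosolic ribosomal proteins had a median of 474 ± 61.6 TPM, with Rpl41 at 2293 ± 393 TPM and Rps25 at 1671 ± 350 TPM.

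Genes of young neurons stood highest among the cell type lists. All 14 members of the general neuronal list were detected, at a median of 167 ± 46.7 TPM, percentile 100 among random lists. Tubb3, the neuronal beta tubulin, stood at 1687 ± 86.8 TPM, the growth cone gene Gap43 at 1446 ± 237 TPM, Stmn2 at 1262 ± 137 TPM, and Mapt, which encodes tau, at 965 ± 258 TPM. The 10 transcription factors of the telencephalon were all detected at a median of 40.6 ± 7.88 TPM, percentile 99.1, with Neurod6 at 256 ± 84.0 TPM, Bcl11a at 141 ± 2.84 TPM, Neurod2 at 61.7 ± 0.318 TPM and Nfib at 44.5 ± 17.7 TPM. Deep-layer cortical genes had a median of 34.1 ± 9.26 TPM, percentile 98.6, including Crym at 121 ± 28.8 TPM, Ldb2 at 87.5 ± 6.41 TPM, and Bcl11b, a factor of neurons that project below the cortex, at 47.0 ± 15.4 TPM. Upper-layer genes had a median of 10.2 ± 1.64 TPM, percentile 78.0, with Cux1 at 68.5 ± 3.63 TPM and Pou3f3 at 20.5 ± 2.45 TPM. Reln, secreted by Cajal-Retzius cells, stood at 30.9 ± 3.68 TPM, and 6 of the 7 genes of that list were detected, at a median of 3.19 ± 1.09 TPM.

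Genes of the inhibitory and striatal lineages were expressed too, though list medians of different genes do not measure how much of a lineage is present. All 16 genes of the GABAergic list were detected at a median of 22 ± 3.96 TPM, percentile 98.3, with the neuropeptides Sst at 417 ± 13 TPM and Npy at 389 ± 173 TPM, Dlx1 at 99.4 ± 22.4 TPM, and Gad1, an enzyme of GABA synthesis, at 85.9 ± 20.8 TPM. All 12 striatal genes were detected at a median of 25.8 ± 2.75 TPM, percentile 98.0, with Foxp1 at 123 ± 20.3 TPM, Tac1 at 86.9 ± 1.91 TPM and Ppp1r1b, which encodes DARPP-32, at 85.8 ± 14.6 TPM. Glutamate transport and receptor genes had a median of 36.7 ± 8.92 TPM, with Gria2 at 106 ± 35.8 TPM and Gria1 at 57.7 ± 26.6 TPM. GABA-A receptor and chloride transporter genes had a median of 24.6 ± 9.69 TPM, with Gabra5 at 90.3 ± 6.54 TPM. All 20 axon guidance genes were detected at a median of 20.4 ± 7.23 TPM, with the adhesion molecules Ncam1 at 380 ± 74.7 TPM and L1cam at 71.6 ± 15.9 TPM.

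Genes of progenitors and glia were expressed beside them. All 12 radial glia genes were detected at a median of 17.8 ± 4.02 TPM, percentile 94.2, led by Fabp7, a lipid-binding protein of radial glia, at 2239 ± 124 TPM and Vim at 200.0 ± 31.0 TPM. Intermediate progenitor genes had a median of 6.4 ± 0.460 TPM, with Hes6 at 134 ± 9.92 TPM and Gadd45g at 28.1 ± 0.283 TPM. Cell cycle genes had a median of 15.3 ± 0.806 TPM, with Pcna at 105 ± 4.07 TPM, Cdk1 at 41.7 ± 3.20 TPM and Rrm2 at 40.9 ± 0.877 TPM. All 12 astrocyte genes were detected at a median of 52.6 ± 10.3 TPM, percentile 99.9, with Apoe at 1127 ± 152 TPM, Sparcl1 at 211 ± 30.6 TPM and Aldoc at 163 ± 26.0 TPM. Oligodendrocyte precursor genes had a median of 7.43 ± 2.02 TPM, with Cspg5 at 208 ± 32.1 TPM, Olig1 at 107 ± 8.84 TPM and Pdgfra at 9.76 ± 2.52 TPM. Myelin genes stood lower, at a median of 0.675 ± 0.184 TPM with 4 of 9 detected in both pups, among them Cnp at 41.0 ± 7.64 TPM, Mbp at 15.8 ± 3.16 TPM and Mag at 2.56 ± 0.544 TPM. Mobp, a component of compact myelin, stood at 0.0950 ± 0.0778 TPM and Opalin at 0.0100 ± 0.0141 TPM.

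Cells of vessels, meninges, ventricles, blood and the immune system were also represented. Microglial genes had a median of 11.0 ± 0.534 TPM, with the complement gene C1qb at 58.9 ± 4.63 TPM and Tyrobp at 39.1 ± 3.66 TPM. Endothelial genes had a median of 8.92 ± 0.926 TPM with the tight junction gene Cldn5 at 106 ± 3.53 TPM. Pericyte genes had a median of 6.91 TPM with Vtn at 97.2 ± 8.11 TPM, and genes of meninges and fibroblasts 27.6 ± 2.25 TPM with Igf2 at 122 ± 4.80 TPM, Dcn at 55.2 ± 18.5 TPM and Col3a1 at 45.6 ± 1.39 TPM. Choroid plexus genes had a median of 8.74 ± 2.10 TPM, led by Ttr, the thyroxine carrier of the cerebrospinal fluid, at 1169 ± 200 TPM, and ependymal genes 8.33 ± 1.86 TPM, with Foxj1, the factor for motile cilia, at 14.5 ± 2.79 TPM. Adult globins stood at 1162 ± 252 TPM (Hba-a2) and 790 ± 232 TPM (Hbb-bs), the embryonic globin Hbb-y at 0.870 ± 0.212 TPM, and the erythroid list at 6.82 ± 0.629 TPM. Hba-a1 and Hba-a2, and the adult beta globins, are near-identical copies, so reads are split between them.

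Regional genes of the thalamus and hypothalamus were expressed, and those of the midbrain and hindbrain stayed under the detection limit. Thalamic genes had a median of 14.6 ± 7.19 TPM with all 7 detected, led by Tcf7l2, a factor of the developing thalamus and habenula, at 161 ± 102 TPM, and Slc17a6, the vesicular glutamate transporter VGLUT2, at 33.7 ± 16.4 TPM. Hypothalamic genes had a median of 3.49 ± 1.59 TPM with 7 of 13 detected in both pups, led by Avp, which encodes vasopressin, at 108 ± 59.2 TPM and Trh at 9.45 ± 1.77 TPM. None of the 16 midbrain and hindbrain genes was detected in both pups. The highest of these was Tph2, the serotonin-synthesising enzyme of the raphe, at 0.740 ± 0.170 TPM, and the midbrain factor En1 stood at 0.0950 ± 0.0778 TPM. None of 6 retina and lens genes was detected, with Cryaa at 0.160 ± 0.0849 TPM. Neighbouring tissues left few traces: 2 of 6 olfactory epithelium genes were detected, with Gng13 at 16.7 ± 3.86 TPM and Omp, the marker of mature olfactory neurons, at 0.280 ± 0.0283 TPM. Detected were also 2 of 7 skeletal muscle genes (Acta1 at 15.3 ± 2.31 TPM), 2 of 6 skin genes (Krt10 at 32.2 ± 3.15 TPM), 2 of 7 cartilage and bone genes (Col2a1 at 3.05 ± 1.46 TPM) and 1 of 7 pituitary genes (Pomc, which the hypothalamus also expresses, at 3.48 ± 0.714 TPM). Of 7 liver genes, 3 were detected, but Alb stood at 0.02 TPM in both pups and the highest, Ttr, is a choroid plexus gene.

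Lists of cell states completed the description. Imprinted genes had a median of 28.6 ± 9.86 TPM, percentile 99.5, with Nnat, Snrpn at 619 ± 113 TPM, Ndn at 478 ± 69.4 TPM and Meg3 at 466 ± 215 TPM. Nuclear long noncoding RNAs had a median of 7.28 ± 3.11 TPM, led by Malat1, a nuclear speckle RNA, at 1773 ± 1263 TPM. The leading Malat1 transcript was 485 bases long. Genes of heat shock and the unfolded protein response had a median of 51.4 ± 11.3 TPM, with the constitutive chaperone Hspa8 at 1889 ± 99.6 TPM and the heat-induced Hspa1b at 0.380 ± 0.0424 TPM. Genes of hypoxia and glycolysis had a median of 17.5 ± 4.32 TPM, with Ldha at 625 ± 4.18 TPM and Pgk1 at 186 ± 6.72 TPM. Immediate early genes had a median of 7.66 TPM, with Jun at 39.4 ± 2.86 TPM, Egr1 at 20.6 ± 0.792 TPM, and the activity-induced Npas4 at 0.315 ± 0.0212 TPM. Interferon and immune genes had a median of 3.26 ± 0.354 TPM, with B2m at 134 ± 11.0 TPM and Ifit1 at 0.695 ± 0.0495 TPM. Of 67 replication-dependent histone genes, whose messages mostly lack a polyA tail, 32 were detected at a list median of 0.875 ± 0.247 TPM, with Hist1h2ap at 783 ± 341 TPM and Hist3h2ba at 104 ± 17.3 TPM. Posterior mean TPM moved the median level of 12 of 43 lists by more than the spread between pups, and M4 did so for 5. Leaving out either pup did so for 5 lists (pup 1) or 7 lists (pup 3). With 2 pups, leaving 1 out can pass that spread only where the median comes to rest on other members. Lists that did not move are therefore no sign of stability.

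**Figure D1:**
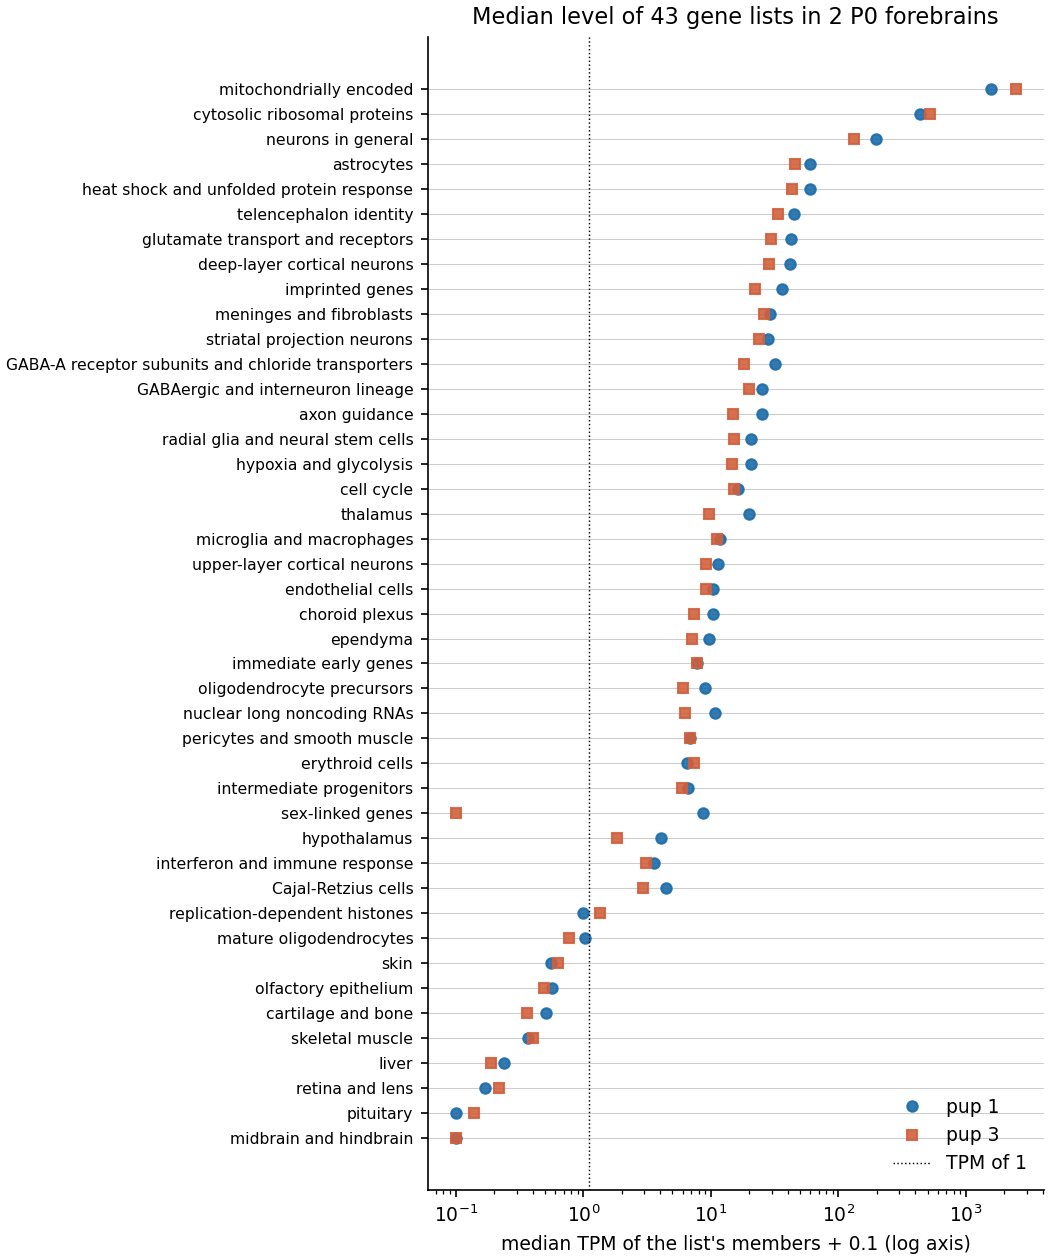
Median TPM of each gene list (log axis, plotted as TPM + 0.1) in the forebrain of P0 mice, with a point for each of the 2 pups, lists sorted by level and a dotted line at a TPM of 1. Mitochondrially encoded, ribosomal protein and general neuronal genes lie highest, at medians over both pups of 2017, 474 and 167 TPM, and the midbrain and hindbrain list lies at 0.

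In several gene pairs whose balance shifts as the brain matures, the earlier gene was the higher one. Grin2b, the early subunit of the NMDA receptor, exceeded Grin2a, the later one, at 67.1 ± 24.7 against 1.93 ± 1.58 TPM, a log2 ratio of 5.26 ± 0.72 (SD, n = 2 pups). Slc1a3, the glutamate transporter of radial glia and early astrocytes, exceeded Slc1a2, that of mature astrocytes, by a log2 ratio of 3.78 ± 0.58. The early sodium channel gene Scn3a exceeded Scn1a by 1.47 ± 0.02, and Dcx, a gene of migrating neurons, exceeded Rbfox3, which encodes NeuN, by 1.25 ± 0.22. The chloride transporters stood the other way: Slc12a2 (NKCC1), which loads neurons with chloride, lay at 4.40 ± 0.820 TPM and Slc12a5 (KCC2), the later extruder, at 26.9 ± 10.5 TPM, a log2 ratio of -2.54 ± 0.31. Slc12a2 is made by glia as well, and bulk RNA does not separate the cells. The log2 ratio of Slc17a6 to Slc17a7, the vesicular glutamate transporters of subcortical and cortical neurons, was 0.20 in pup 1 and -0.85 in pup 3. In expected counts, which are not corrected for length, Scn3a/Scn1a was 2.69, Dcx/Rbfox3 2.76 and Slc12a2/Slc12a5 -1.67, while the mean of Slc17a6/Slc17a7 changed sign, from -0.32 in TPM to 0.12. The leading Grin2b transcript was 241 bases long, so part of its TPM rests on a short entry.

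**Figure D2:**
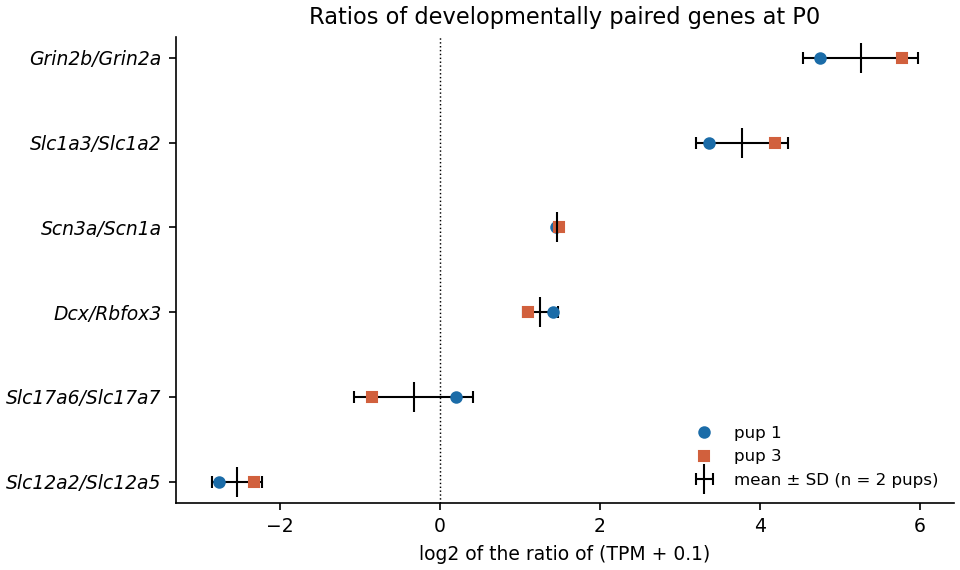
Log2 ratio of TPM + 0.1 of the first to the second gene of each of 6 pairs within a library; points are the 2 pups, ticks and bars their mean and SD. Grin2b/Grin2a lies highest at 5.26 and Slc12a2/Slc12a5 lowest at -2.54.

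Among genes with 50 or more counts, the pups differed most in genes of the sex chromosomes. Xist (X chromosome, 103460366 to 103483254), the RNA that coats the inactive X, had 2 counts in pup 1 and 4428 in pup 3, 2200-fold apart by counts (exact 95% interval 609 to 18169). The Y-linked genes stood the other way. Ddx3y (Y chromosome, 1260771 to 1286629), an RNA helicase, had 3115 counts in pup 1 and 0 in pup 3, at least 1045-fold higher in pup 1. Eif2s3y, a translation factor (1010543 to 1028847), was at least 857-fold higher and Kdm5d, a histone demethylase (897788 to 956786), at least 227-fold higher in pup 1, each with 0 counts in pup 3. Uty (1096861 to 1245759), another histone demethylase family member, had 619 counts in pup 1 and 1 in pup 3, 623-fold apart (111 to 24647). The Y chromosome held 7021 counts in pup 1 and 3 in pup 3. Tsix, which overlaps Xist on the other strand, stood at 0.1 TPM in pup 1 and 10.1 TPM in pup 3, and its reads cannot be told from those of Xist where strand is not known.

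Across genes as a whole the pups were close in level but differed by more than counting error. Over 15463 genes with a mean TPM of 1 or more, the sex-linked ones included, Pearson r was 0.983 and Spearman rho 0.982 across genes, and 97.1% of genes lay within 2-fold. The SD of the log2 ratio was 0.39, a 1.31-fold spread, and the fitted BCV was 0.176 over 17684 genes. For 9687 genes with 1000 or more counts over both pups, a chi-square compared their counts with the split of total counts. Its median was 18.6, against 0.455 under counting noise, and 75.2% of these genes lay above the 95% point. That split was not scaled, so a shift shared by most genes, with a median log2 ratio of -0.10 in unscaled CPM, adds to these values. How much it adds was not tested. The median log2 ratio of TPM was -0.24 and 79.6% of genes were lower in pup 3. The median was -0.10 in CPM without scaling and 0.01 in CPM with TMM scaling, so both the unit and the scaling moved it. Differences of single genes are therefore given below relative to the median of all genes, and those of lists relative to lists matched on expression. The log2 ratio was also lower for longer transcripts: its Spearman rho across genes was -0.41 with transcript length and 0.14 with GC content. Protein-coding genes with leading transcripts under 1000 bases had a median of -0.02 and those of 6000 bases or more -0.49.

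**Figure D3:**
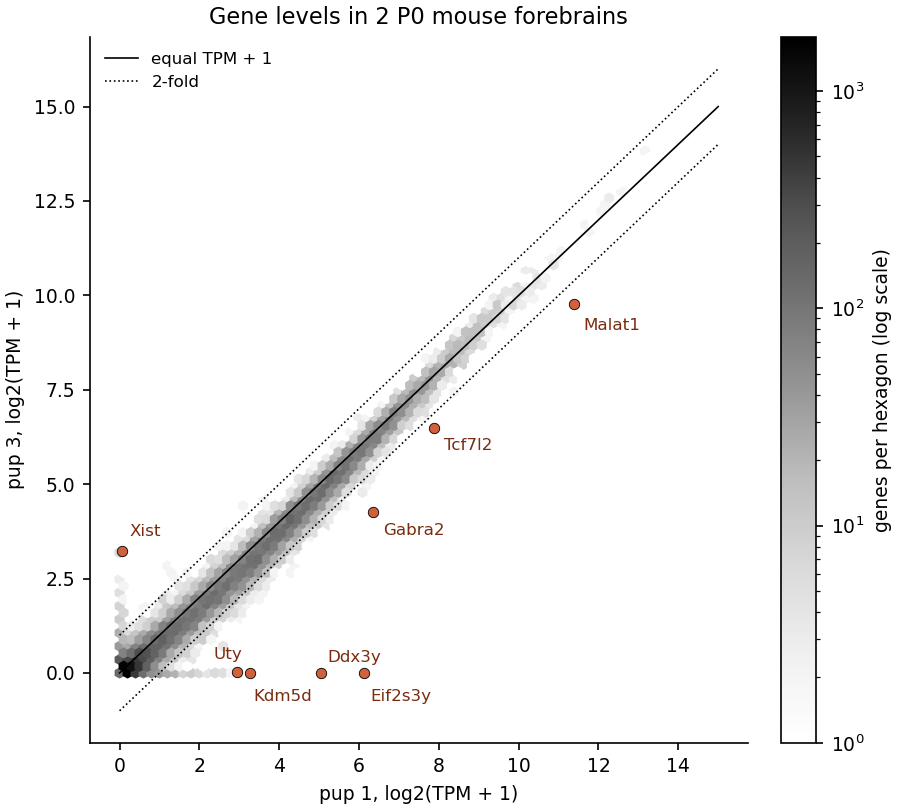
Log2(TPM + 1) of each gene in pup 3 against pup 1, as hexagons shaded by the number of genes (log scale), with the line of equal values, dotted lines at 2-fold and named genes as points. Most genes lie along the line (Pearson r 0.983), Xist lies near 0 in pup 1, and the 4 Y-linked genes lie at or near 0 in pup 3.

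Lists of the thalamus, the hypothalamus and nuclear long noncoding RNAs were lower in pup 3 by more than matched genes. The thalamic list had a median log2 ratio of -0.75 relative to matched lists, percentile 0, with 6 of 7 genes below the all-gene median. Tcf7l2 stood at 233 TPM in pup 1 and 89.6 TPM in pup 3, a log2 ratio of -1.13 relative to all genes, and Slc17a6 at 45.3 and 22.1 TPM, a relative log2 ratio of -0.76. Prkcd, a marker of thalamic relay neurons, was the exception, at 16.3 and 15.3 TPM. The hypothalamic list also had a relative median of -0.75, percentile 0, with 8 of 8 compared genes below the all-gene median. Avp stood at 150 TPM in pup 1 and 66.0 TPM in pup 3, a relative log2 ratio of -0.93, and Fezf1, a factor of hypothalamic development, at 8.29 and 3.59 TPM, a ratio of -0.78. The telencephalon list lay at the 86.7th percentile of matched lists, with 4 of 10 genes below the all-gene median. Nuclear long noncoding RNAs had the lowest relative median outside the sex-linked list, -0.80. Of 7 compared, 6 lay below the all-gene median and Xist above it, and 3 of the 8 listed, Meg3 and Xist among them, belonged to other lists as well. Among the lower ones were Malat1 at 2666 and 880.1 TPM (relative log2 ratio -1.36), Meg3 at 619 and 314 TPM (-0.74), Snhg11 at 148 and 31.7 TPM (-1.95) and Rmst at 13.1 and 3.95 TPM (-1.27).

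Neuronal signalling genes were lower in pup 3 as well. The glutamate list had a relative median of -0.56, percentile 0, with 9 of 10 genes below the all-gene median, among them Gria2 (131 and 80.7 TPM, relative log2 ratio -0.46), Grin2b (84.6 and 49.7 TPM, -0.52) and Gria1 (76.6 and 38.9 TPM, -0.72). The general neuronal list had a relative median of -0.49, percentile 0, with 11 of 14 genes below the all-gene median; Mapt stood at -0.31 relative to all genes, while Tubb3 stood at 0.13. With a trend on deposited gene length and GC content removed, the relative median of that neuronal list was -0.31. GABA-A and chloride transporter genes had a relative median of -0.28, percentile 0.170, with 10 of 12 genes below the all-gene median, and Gabra2 at 80.6 and 18.2 TPM, a relative log2 ratio of -1.85. Axon guidance genes had a relative median of -0.24, percentile 0.110, with 19 of 20 genes below the all-gene median, and deep-layer cortical genes -0.24, percentile 0.720. With the trend on length and GC content removed, a setting chosen after the data were seen, these last 3 lists lay within the central range, at percentiles 4.10, 2.55 and 5.24. Imprinted genes had a relative median of -0.26, percentile 0.180, and astrocyte genes -0.19, percentile 1.82. The sex-linked list, with 4 Y-linked genes of 5, had a relative median of -2.96.

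Genes of ribosomes, mitochondria, the cell cycle, histones, pericytes and red blood cells stood higher in pup 3 than matched genes. All 80 compared ribosomal protein genes lay above the all-gene median, with a relative list median of 0.26, percentile 100, and Rps25 at 1423 and 1918 TPM. Mitochondrially encoded genes had a relative median of 0.24, percentile 99.6, with 12 of 13 above the all-gene median, mt-Atp6 at 11813 and 16690 TPM, and mt-Nd4l, a gene of complex I chosen after its values were seen, as the exception at 83.6 and 24.9 TPM. Replication-dependent histones had a relative median of 0.52, percentile 100, with 31 of 33 above the all-gene median and Hist1h2ap at 542 and 1024 TPM. Cell cycle genes had a relative median of 0.27, percentile 99.9, with 13 of 15 above the all-gene median, including Pcna (relative log2 ratio 0.32) and Cdk1 (0.39). All 5 compared erythroid genes lay above it, with a relative median of 0.48, percentile 99.99, Hba-a2 at 984 and 1341 TPM and Hbb-bs at 626 and 954 TPM. Relative medians were 0.33 for immediate early genes, 0.33 for pericytes, 0.28 for meninges and 0.23 for microglia, at percentiles 99.8, 99.6, 99.9 and 99.6. In 8 of 8 immediate early genes the ratio lay above the all-gene median, with Egr1 at 0.31 and Ier2 at 0.41. With a trend on the deposited gene length and GC content removed, a setting chosen after the data were seen, the relative medians were 0.15 for ribosomal proteins, 0.31 for histones, 0.27 for erythroid genes and 0.14 for microglia. Of these, microglia then lay within the central range, at percentile 97.1.

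The 37 compared lists included 20 outside the central 95% of matched lists, 11 lower and 9 higher in pup 3 than matched lists. Of the higher ones, microglia and cell cycle had median log2 ratios of -0.04 and -0.003 before matching, so they were higher only relative to matched lists. The other 17 lists lay inside the central 95%. Inside were radial glia (percentile 2.63), intermediate progenitors (97.2), telencephalon identity, upper-layer neurons (48.3), Cajal-Retzius cells (5.25), GABAergic lineage (14.2), striatal neurons (22), oligodendrocyte precursors (8.97) and mature oligodendrocytes (33.8). Endothelial cells (94.8), choroid plexus (10.4), ependyma (24.0), skeletal muscle (46.8), liver (26.4), hypoxia and glycolysis (82.0), heat shock (55.4) and interferon genes (65.1) lay inside as well. With TMM scaling, intermediate progenitors and endothelial cells came to lie above the central range and Cajal-Retzius cells below it. The same 3 lists did so with the length and GC trend removed, as did choroid plexus and ependyma, at percentiles 1.21 and 2.08. With the trend on deposited gene length removed, upper-layer neurons lay above the range, at percentile 98.9, and Cajal-Retzius cells inside it, at 10.9. Single genes within such lists still differed: Neurod6 stood at 197 and 316 TPM and Npy at 267 and 511 TPM in pup 1 and pup 3. These are single libraries per pup, so the percentiles place each list among genes of this pair of libraries and say nothing of other pups.

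**Figure D4:**
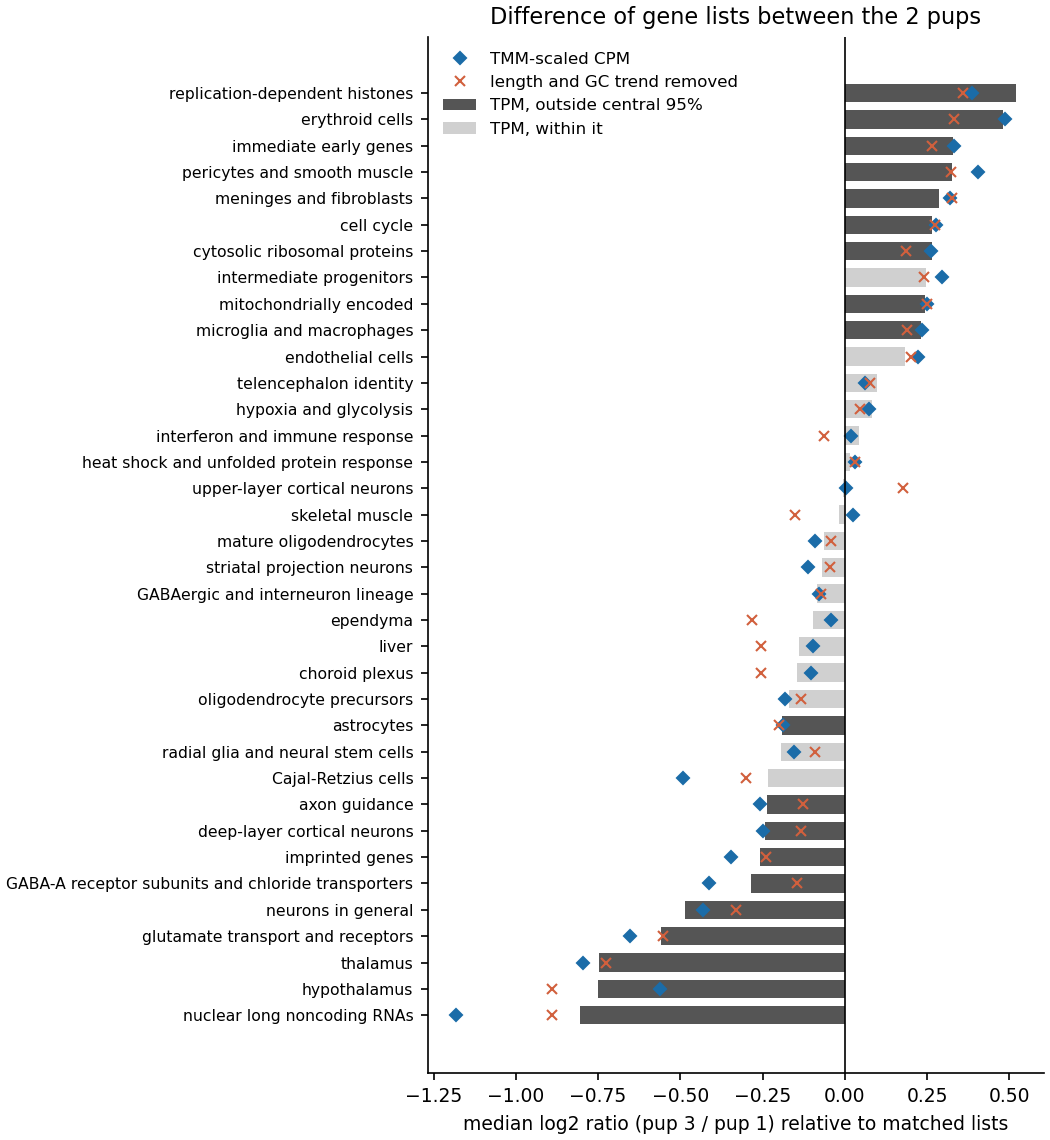
Median log2 ratio of pup 3 to pup 1 of each compared gene list relative to matched random lists (bars; dark outside the central 95% of matched lists), with values under TMM scaling (diamonds) and with the length and GC trend removed (crosses); the sex-linked list is left out. Nuclear long noncoding RNAs, hypothalamus and thalamus lie lowest in TPM, at -0.80, -0.75 and -0.75, and histones and erythroid genes highest, at 0.52 and 0.48.

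Counted gene by gene, 38 genes were over 2-fold higher and 249 over 2-fold lower in pup 3, of 11477 with a TPM of 5 or more in at least 1 pup. Relative to the median of all genes the counts were 63 and 97, and 31 and 81 among genes with 50 or more counts. In CPM they were 18 and 133 without scaling and 26 and 77 with TMM scaling. The number of lower genes thus depended on both unit and scaling, and lower genes outnumbered higher ones in each of these settings. Of the 249 lower genes, 73 remained over 2-fold lower in TMM-scaled CPM. The minimum of 50 counts, the removal of the median and unscaled CPM were settings chosen after the data were seen. The 12 genes with the largest difference in each direction were mostly short entries with few reads: 10 of the 12 higher and 8 of the 12 lower ones had leading transcripts under 260 bases and under 50 counts. Mir8104, a microRNA entry on chromosome 10, reached 33.3 TPM in pup 3 on 1.96 counts, and Gm42845, a pseudogene on chromosome 5, 48.9 TPM in pup 1 on 7.66 counts. Gm26359, Gm44397, Gm27517, Gm25328 and Gm15432 were of this kind among the higher genes, and Gm24667, Gm26940 and Gm27582 among the lower ones. The snoRNA genes Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 stood in both sets, since each is listed under a pair of nearly identical overlapping entries and each pup's reads fell on a different one. The remaining genes were Xist, Tsix and the 4 Y-linked genes.

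Both pups used mostly the same leading isoforms. Of 9322 genes with more than 1 listed transcript and a TPM of 5 or more in both pups, 8676 (93.1%) had the same leading transcript. Where it took over 60% of the gene's TPM in both pups, it was the same in 5327 of 5334 genes. Among 16 genes known for isoforms regulated in the brain, 13 had the same one. Snap25, of the synaptic vesicle fusion machinery, gave 77.8% ± 2.34 of its TPM to 1 of 3 transcripts, Ncam1 74.5% ± 0.333 to 1 of 7, Ptbp2, a neuronal splicing regulator, 66.1% ± 3.36 to 1 of 13, and Clta, clathrin light chain, 66.0% ± 0.0672 to 1 of 6. Shares were 62.6% ± 1.91 for Bcl11a, 60.9% ± 1.87 for Src, 57.9% ± 4.66 for Gria2, 47.7% ± 0.560 for Mapt, 46.0% ± 5.83 for Dcx and 40.9% ± 10.2 for Map2. They were 33.6% ± 3.45 for Grin1, 32.6% ± 0.0693 for Rbfox1 and 27.9% ± 3.60 for Mef2c. Dnm1, which encodes a dynamin of synaptic vesicle recycling, was among the 3 genes with different leading transcripts, which took 19.4% of its TPM in pup 1 and 23.8% in pup 3.

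The 2 deposited annotations gave close values for most genes. Spearman rho across shared genes was 0.972 in pup 1 and 0.971 in pup 3, and TPM + 1 differed over 2-fold for 345 of 11341 and 334 of 10546 genes. Single genes, chosen after their values were seen, moved far. Ptp4a1, a phosphatase gene, stood at 2.43 ± 0.891 TPM with M21 and 274 ± 17.7 TPM with M4, Tonsl at 7.69 ± 3.17 and 301 ± 1.39 TPM, Usp50 at 1.41 ± 0.495 and 202 ± 12 TPM, and Ulk4 at 84.8 ± 2.65 and 5.0 ± 0.573 TPM.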

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

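Features whose identifiers are a number alone were used in no comparison of the report. In pup 1 they held 4.61 expected counts, over 3 of the 26248 features, above the 3 counts that a count of 0 allows. In pup 3 they held 2.26 counts over 2 features, under that limit. No biological explanation was tested.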

How the results depend on the processing

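The minimum of 50 counts, protein-coding genes alone, unscaled CPM, the removal of the all-gene median and both removals of a length trend were chosen after seeing the data. The number of genes detected in both pups (14753) ranged from 10442 to 18234 over the alternatives, and from 15010 to 15864 with either replicate left out. Pearson r was 0.968 with a pseudocount of 0.1, 0.989 with 5, 0.990 without a filter, 0.985 in FPKM and 0.988 in CPM. Spearman rho was 0.939 without a filter, 0.972 at a mean TPM of 10 or more and 0.988 in CPM. The SD of the log2 ratio was 0.59 with a pseudocount of 0.1, 0.26 with 5, 0.34 without a filter, 0.33 at a mean TPM of 10, 0.36 in FPKM, 0.34 in CPM and 0.38 with M4. The BCV was 0.192 with library size alone, 0.199 without a filter and 0.170 with M4. Genes over 2-fold higher in pup 3 (38) numbered 18 with a pseudocount of 5, 107 at a TPM minimum of 1, 6 at 20, 13 at 50 or more counts, 5 among protein-coding genes, 18 with the length and GC trend removed, 18 with the trend on deposited gene length removed, 18 in unscaled CPM and 63 relative to the all-gene median. Genes over 2-fold lower (249) numbered 133 in unscaled CPM, 77 in CPM with TMM scaling, 76 with DESeq2 size factors, 97 relative to the all-gene median, 392 with a pseudocount of 0.1, 70 with 5, 445 at a TPM minimum of 1, 95 at 20, and 165 with the trend on deposited gene length removed. Lower genes made up 86.8% of both in TPM, 74.8% in TMM-scaled CPM, 88.1% in unscaled CPM, 60.6% relative to the all-gene median and 94.7% at 50 or more counts. Expected counts gave log2 ratios of 4.16 for Grin2b/Grin2a, -1.67 for Slc12a2/Slc12a5, 2.69 for Scn3a/Scn1a, 2.76 for Dcx/Rbfox3, 2.62 for Slc1a3/Slc1a2 and, with the sign changed but within the spread between pups, 0.12 for Slc17a6/Slc17a7; they are not corrected for length by construction. M4 gave 4.45 for Grin2b/Grin2a, -2.08 for Slc12a2/Slc12a5 and 1.56 for Scn3a/Scn1a, which was 1.37 with a pseudocount of 1. At a TPM minimum of 20, 95.1% of genes shared the leading isoform. Apart from the expected counts, the cause was not tested. All 20 lists outside the central range stayed outside in the same direction with TMM scaling, DESeq2 size factors, a pseudocount of 0.1, no filter and M4, 17 did with the length and GC trend removed and 16 with the trend on deposited gene length removed. Other lists came to lie outside: 3 with TMM scaling, 3 with DESeq2 size factors, 2 with M4 and 5 with either trend removed. List levels moved beyond the spread between pups for 12 of 43 lists with posterior mean TPM and 5 with M4. Of 227 named genes, 36 lay over 2-fold apart, 13 of them also with TMM scaling and 12 with DESeq2 size factors, and none was over 2-fold in the opposite direction. Low counts limit features of about 100 bases, where 1 or 2 reads exceed a TPM of 5.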

Other observations

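The tests below compare a single library per pup. The mixture test was chosen after its result was seen, and the length and GC corrections and the second diencephalic list were chosen after the first comparison of the pups.

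Among genes with 50 or more counts, chosen after their values were seen, some outside the fixed lists differed by over 2-fold, with log2 ratios given relative to the median of all genes. Hspb3, a small heat shock protein gene, stood at 2.47 TPM in pup 1 and 9.72 TPM in pup 3, a log2 ratio of 1.86. S100a8 and S100a9, which encode the calprotectin of neutrophils, stood at 3.56 and 11.1 TPM and at 2.97 and 9.12 TPM, log2 ratios of 1.64 and 1.59. The noncoding RNA 9130024F11Rik stood at 29.3 and 83.2 TPM, a log2 ratio of 1.71. Within the fixed thalamic list, Lhx9, a factor of the thalamus, stood at 22.1 and 5.05 TPM, a log2 ratio of -1.70. It is already part of that list's median and adds no separate evidence.

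More genes were over 2-fold lower than higher in pup 3. If a few abundant RNAs took more of the total, TMM scaling would bring lower genes to at most 1.5 times the higher ones, but the ratio was 2.96 in TMM-scaled CPM, which argues against this as the whole cause, though in TPM with the median removed 97 lower stood against 63 higher genes, close to that limit. If a trend on transcript length or GC content were the whole cause, its removal would leave under 50% of the lower genes with 50 or more counts. Of these, 66.4% remained (152 of 229), and 58.7% (135 of 230) with deposited gene length. The removal kept the all-gene offset, a median log2 ratio of -0.20, so these shares cannot weigh the trend by itself. With the median of all genes removed as well, 84 lower genes were counted, against 81 with the median alone removed. Removing the trend thus did not reduce their number. The unit and the scaling did contribute to the number of lower genes, which was 249 in TPM, 133 in unscaled CPM and 77 in TMM-scaled CPM. Of the 249, 73 remained over 2-fold lower in TMM-scaled CPM, and 97 lower genes were counted in TPM with the median removed. What set the remaining excess of lower over higher genes stays open. The design names no group to set against these, so no biological explanation was tested.

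Thalamic and hypothalamic genes were lower in pup 3. With the length and GC trend removed, their joint median lay at percentile 0 of matched lists, which argues against that trend as the cause. If the pup 3 sample held a smaller share of diencephalic tissue, other diencephalic genes would be low and telencephalic genes would not. A second list of 16 such genes, 9 of them compared, lay at percentile 0.0100 with a median log2 ratio of -0.53 relative to matched lists (7 of 9 below the all-gene median), and the telencephalon list at percentile 86.7, but the deep-layer cortical list, also telencephalic, lay at 0.720 (5.24 with the trend removed). Lists not written for the diencephalon were also low, each at percentile 0. These were general neuronal genes (-0.49), nuclear long noncoding RNAs (-0.80) and the glutamate list (-0.56), which shares Slc17a6 with the thalamic list. The GABAergic and striatal lists lay inside the central range, at percentiles 14.2 and 22. The second list therefore does not single out diencephalic tissue. A smaller diencephalic share may account for the thalamic and hypothalamic genes, as a hypothesis found on the same data. It leaves the deep-layer, neuronal, glutamate and noncoding RNA lists aside. A lower expression of the thalamic and hypothalamic genes in pup 3 stays open and untested.

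Y-linked genes were seen in pup 1 and Xist in pup 3, while sex was not collected. If each library mixed RNA of both pups, each sex-linked gene would reach 1% of its higher library in the other, but 5 of 5 genes lay under 1%, which argues against a mixture at that level. If pup 3 had a pair of X chromosomes and pup 1 an X and a Y, X-linked genes that escape inactivation would be higher in pup 3. Their median log2 ratio relative to all genes was 0.50 with the length and GC trend removed and 0.31 against matched lists without that correction; with the trend removed Kdm6a stood at 0.47, Kdm5c at 0.47, Ddx3x at 0.53 and Eif2s3x at 0.76. The 5 sex-linked genes, each under 1%, also argue against both libraries coming from 1 animal, although the labels give both pups the same donor identifier. A female pup 3 and a male pup 1 would give all of these values, though the labels do not state sex. Every difference between the pups would then also be one between a male and a female, and these cannot be told apart here.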
